A study of Rattus norvegicus with 21 samples.

How the data were processed

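Primary rat astrocytes of passages 2-3 were transfected with siRNA, per the labels' protocols. Poly(A) libraries were made with a TruSeq kit and the total RNA libraries of the immunoprecipitation with a ScriptSeq kit. The 21 libraries form 7 groups of 3, taken from the sample labels: scrambled siRNA, TDP-43 siRNA, and TDP-43 siRNA and ATP in poly(A) RNA, and input and J2-immunoprecipitated RNA of control and TDP-43 siRNA cells. The labels do not say whether the control of the immunoprecipitation received scrambled siRNA, and the dose and duration of ATP are not given in the sources used here. The authors deposited 3 tables of raw counts: genes by symbol in the 9 poly(A) libraries, and repeat elements by name in those 9 and in the 12 immunoprecipitation libraries. The submitters' processing notes name Trimmomatic, TopHat2, Bowtie2, DESeq2 and the rn6 build, with no versions or roles. The counting tool, its treatment of reads that map to several places, its use of strand and the repeat annotation are not given in the sources used here, so counts of paralogs, histone genes and related repeat elements that share reads are uncertain.

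The gene table held 17311 rows, and 14821 symbols matched a reference gene table of the GRCr8 assembly, used for names only. A further 26 rows whose symbols had become calendar dates were left out; they held 0.286 to 0.331% of counts. Each repeat table held 1275 names. No coordinates were used. Total counts per library ran from 11.5 to 40.3 M for genes, from 3.3 to 39.1 M for poly(A) repeats, from 9.47 to 11.7 M for input and from 1.85 to 3.37 M for immunoprecipitated RNA. No 2 libraries of a group were alike within sampling noise (chi-square per degree of freedom at least 11.4), so each counts as 1 replicate.

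Counts were tested with edgeR 4.0.16 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. Each table was scaled and fitted separately, with 1 mean per group and a spread shared by all its libraries. This left 12096 genes, 1137 poly(A) repeats and 1176 immunoprecipitation repeats. There were 3 gene comparisons, 3 poly(A) repeat comparisons and 5 immunoprecipitation comparisons, the last being the difference of the enrichments. Standard errors were derived from the log2 fold change and its F statistic. CPM are on TMM-scaled totals. Tardbp, repeat counts per gene count and class shares were compared with two-sided exact permutation tests, whose smallest p at 3 against 3 is 0.1.

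A set of 28 gene lists with 672 entries, 35 of them not found in the table, was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists. The lists covered interferon response, double-stranded RNA sensing, NF-kappaB with cytokines and chemokines, pan-reactive, A1 and A2 astrocyte genes, complement and antigen presentation, and markers of astrocytes, microglia, the oligodendrocyte lineage, neurons, and fibroblast, mural and endothelial cells. They also covered the integrated stress and unfolded protein responses, cell cycle, p53 targets, immediate early genes, purinergic signalling, inflammasome, cholesterol synthesis, RNA-binding proteins linked to TDP-43, transcripts regulated by it, the respiratory chain, glycolysis, autophagy and lysosome, glutamate, extracellular matrix and histone genes. Repeat classes with at least 5 tested elements were tested alike. The tables give element names without classes, so classes were assigned by name rules, which put 17 DNA elements among LTR elements and 106 elements of unclear class among DNA elements. A corrected assignment was tried.

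Groups, tests, lists, class rules and alternatives were fixed before the data were examined. So was the rule for named genes: Tardbp, the 8 largest rises and 8 largest falls that passed with at least 5 CPM and no overlap between groups (leaving out unnamed loci, olfactory receptors and Y-linked genes), up to 4 members of each list that passed or had 3 called members, and 10 immune and astrocyte genes whatever their result. For repeats it was the 5 largest rises and falls with at least 10 CPM, or the 3 smallest p where none passed. Not every gene the rule allows is printed.

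Alternatives were DESeq2 1.42.0, RLE, upper-quartile and total-count scaling, other low-count filters, only the compared libraries, a replicate block, each library left out, a minimum log2 change of 1, gene-table library sizes for poly(A) repeats, repeats without structural RNA and satellites, and for lists an estimated correlation, fry and a prior count of 0.5. Fits without scrambled replicate 1 for further results, the corrected classes and the transposon share were chosen after seeing the data. Overlap between comparisons with shared controls was set against 20 simulated draws of unchanged groups.

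The scripts' tests were tried on simulated data. For knockdown against scrambled siRNA, 48.5% of the genes changed 1.5-fold, 74.6% of those changed 2-fold and 96.9% of those changed 4-fold were recovered, with 11820 genes tested. For poly(A) repeats after knockdown these shares of the changed elements were 26.6, 62.1 and 83.1% (1094 tested), and for immunoprecipitated RNA 30.3, 32.8 and 71.2% (1164 tested). The last simulation used the spread fitted to all 12 libraries, which is below that of the immunoprecipitated ones alone, so real recovery may be lower. Of 24 simulated unchanged lists camera called 1, and it called the raised list. Simulated genes were drawn independently of each other, whereas the estimated correlation of interferon response genes was 0.46 in the real libraries. The trial therefore does not show how often camera calls unchanged lists whose members vary together.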

Results

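RNA of primary Sprague-Dawley rat astrocytes was sequenced after transfection with small interfering RNA (siRNA) against TDP-43, an RNA-binding protein encoded by Tardbp. The 21 libraries fell into 7 groups of 3. In poly(A) RNA, cells had received scrambled siRNA, TDP-43 siRNA, or TDP-43 siRNA and ATP, an extracellular signalling nucleotide. In total RNA, control and TDP-43 siRNA cells were each sequenced before (input) and after immunoprecipitation with J2, an antibody to double-stranded RNA. Counts per library ran from 11.5 to 40.3 M for genes, from 3.3 to 39.1 M for poly(A) repeats and from 1.85 to 11.7 M for repeats of the immunoprecipitation. Nothing in the labels says whether replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

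Tardbp mRNA was measured first, in the poly(A) libraries, since it checks their knockdown labels. It stood at 169 ± 10.7 CPM (counts scaled to 1e6 per library; SD, n = 3) with scrambled siRNA and at 24.8 ± 4.5 CPM (SD, n = 3) with TDP-43 siRNA, 14.6% of the scrambled level. With TDP-43 siRNA and ATP it stood at 26.2 ± 2.38 CPM (SD, n = 3), or 15.5%. Its log2 fold change was -2.77 (SE 0.13, edgeR quasi-likelihood adjusted p = 1.13e-09) without ATP and -2.69 (SE 0.13, edgeR adjusted p = 1.59e-09) with it. The exact two-sided permutation test gave p = 0.1 for both, the smallest that 3 against 3 libraries allow. Between the groups with and without ATP, Tardbp differed by less than the spread between replicates (exact permutation p = 0.7).

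**Figure D1:**
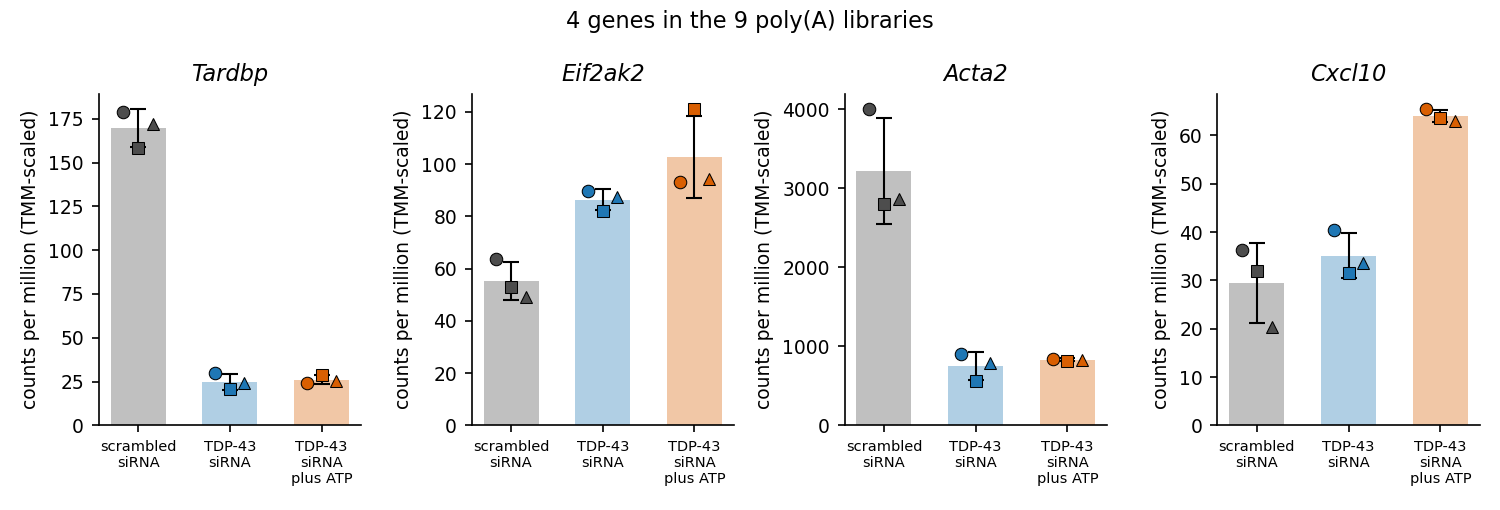
CPM of Tardbp, Eif2ak2, Acta2 and Cxcl10 (y axes, TMM-scaled) in the 9 poly(A) libraries, by group (x axes); bars are means, error bars SD (n = 3), and circles, squares and triangles replicates 1, 2 and 3. Tardbp fell from 169 to 24.8 and 26.2 CPM, and Cxcl10 stood at 64 CPM with ATP against 35.1 CPM without it.

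The first comparison asked how loss of TDP-43 changes the astrocytes' mRNA. The labels name a single TDP-43 siRNA condition and no group with TDP-43 restored. Effects of the siRNA on other transcripts therefore cannot be told apart from those of TDP-43 loss. Enzymes of detoxification and redox metabolism were among the 8 largest rises: Osgin1, an oxidative stress response gene, rose from 2.77 ± 1.53 to 20.9 ± 3.57 CPM (SD, n = 3; log2 fold change 3.06). Gsta1, a glutathione S-transferase, rose from 11.7 ± 0.495 to 81.4 ± 14.2 CPM (log2 2.80), and Akr1b8 (2.85), Srxn1 (2.25) and the cystine transporter gene Slc7a11 (2.23) rose as well. Il1rl1, the receptor of interleukin 33 (2.51), and the stress cytokine Gdf15 (2.40) were also in that set. The deepest falls were those of Wfdc1 (58.1 ± 5.95 to 1.48 ± 0.684 CPM, log2 -5.23), Ctxn3 (-5.23), Faim2 (-4.83), Thrsp (-3.71), Frem3 (-3.66), Pcp4 (-3.63), Lims2 (-3.48) and the matrix proteoglycan gene Fmod (459 ± 61.8 to 41.6 ± 8.16 CPM, log2 -3.46). All of these passed edgeR's test, the largest adjusted p being 1.17e-05, that of Slc7a11. Of 12096 genes tested, 1956 rose and 2198 fell, 356 and 601 of them at least 2-fold. The libraries of the 2 groups did not overlap for 41.6% of genes, where chance gives 10%. Scaling by total counts shifted the median log2 change of all genes to 0.18 and gave 3427 rises and 1436 falls, so directions are relative to the bulk of genes.

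Innate immune genes moved both ways after knockdown. Of 39 tested interferon response genes 3 rose and 9 fell (3 and 9 adjusted over the list alone), and the list did not pass limma's camera test (adjusted p = 0.403). Ifitm3 fell by 1.61 and Cmpk2 by 1.09 on the log2 scale, while Gbp2 rose by 0.72. Of 22 genes of double-stranded RNA sensing 5 rose and 2 fell (5 and 2 adjusted over the list alone), with a camera adjusted p of 0.727. The kinase gene Eif2ak2, which encodes PKR, rose from 55.3 ± 7.45 to 86.4 ± 3.88 CPM (log2 0.64, SE 0.12, edgeR adjusted p = 0.00104), and the RNA editing enzyme gene Adar rose by 0.57, while the PKR activator gene Prkra fell by 0.61 and Mavs by 0.43. The sensor genes Ifih1 (log2 0.03, edgeR adjusted p = 0.85), Tlr3 (0.07, adjusted p = 0.845) and Ddx58 (-0.26, adjusted p = 0.188) did not pass. Of 30 NF-kappaB, cytokine and chemokine genes 4 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.461), among them Cxcl1 (log2 2.11), Vcam1 (-1.04), Csf1 (-0.64) and Cxcl16 (-0.69). Il6 (log2 -1.43, edgeR adjusted p = 0.138), Ccl2 (-0.30, 0.232) and Cxcl10 (0.25, 0.276) did not pass.

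Complement and antigen presentation genes fell together. None of 22 tested members rose and 11 fell (0 and 12 adjusted over the list alone; camera adjusted p = 0.0112), but the adjusted p was 0.763 with an estimated correlation. The classical complement protease genes C1s and C1r fell by 1.42 and 1.33 on the log2 scale, the immunoproteasome subunit gene Psmb9 by 1.09 and its activator gene Psme1 by 0.67. The complement component gene C3 (log2 -0.88, SE 0.22) passed edgeR's test at an adjusted p of 0.00671. Inflammasome genes gave 1 rise and 2 falls of 12 (1 and 2 adjusted over the list alone; camera adjusted p = 0.727), with Gsdmd at -1.06, Casp4 at -0.78 and Txnip at 0.35.

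Markers of astrocytes and of other cells of the culture also changed. Of 20 astrocyte markers 3 rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.159). The water channel gene Aqp4 fell by 1.14, Mlc1 by 1.20 and the glutamate transporter gene Slc1a3 by 0.78 on the log2 scale, while the other main glial glutamate transporter gene, Slc1a2, rose from 8.33 ± 3.96 to 35.1 ± 5.34 CPM (log2 2.14). Gfap, the astrocyte intermediate filament gene, stood at 2330 ± 475 against 2490 ± 337 CPM (log2 -0.10, edgeR adjusted p = 0.678). Of the reactive astrocyte lists, pan-reactive genes gave 2 rises and 5 falls of 13 (Cd44 at 1.06, S1pr3 at -1.12, Hspb1 at -0.95; camera adjusted p = 0.305), A1 genes 2 and 3 of 9 (Fkbp5 at 0.85, Serping1 at -0.90; 0.403) and A2 genes 3 and 1 of 11 (Emp1 at 0.99, Tm4sf1 at -0.48; 0.967). Adjusted over each list alone these were 2 and 5, 2 and 5, and 3 and 1. Fibroblast, mural and endothelial markers fell as a list: 2 of 15 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0204, and adjusted p = 0.763 with an estimated correlation). The smooth muscle actin gene Acta2 went from 3220 ± 679 to 751 ± 175 CPM (log2 -2.10), Tagln fell by 1.70 and Myh11 by 1.69, and the muscle filament gene Des rose by 0.91. Scrambled replicate 1, which stands apart in its repeat counts, carried this call: without it the camera adjusted p was 0.0559. Microglia markers (1 rise, 2 falls of 19; 0 and 0 adjusted over the list alone; camera adjusted p = 0.4), oligodendrocyte lineage markers (3 and 6 of 13; 3 and 7; 0.207) and neuron markers (3 and 2 of 14; 3 and 2; 0.509) did not pass as lists. Single members did, among them Aif1 (-0.59), Sox10 (-1.80), Tubb3 (1.26) and Nefm (2.31).

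RNA-binding protein genes linked to TDP-43 rose as a list, with 6 of 26 members higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.0204, and adjusted p = 0.763 with an estimated correlation). Celf1 rose by 1.24, Hnrnpd by 0.46, Taf15 by 0.39 and Sfpq by 0.30 on the log2 scale. Cell cycle genes gave 7 rises and 0 falls of 34 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0415, and 0.763 with an estimated correlation), led by the centromeric histone gene Cenpa (1.31), with Tpx2 at 0.46, Kif11 at 0.43 and Ccnb1 at 0.32. Targets of the tumour suppressor p53 gave 10 rises and 2 falls of 19 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0415, and 0.763 with an estimated correlation), with Zmat3 at 0.87, Aen at 0.75, the cell cycle inhibitor gene Cdkn1a at 0.68 and Fas at -0.67. Glycolysis and lactate genes fell as a list, with 3 rises and 9 falls of 20 (3 and 9 adjusted over the list alone; camera adjusted p = 0.0401, and 0.763 with an estimated correlation), among them Pdk1 (-1.25), Ldhb (-0.99), Hk1 (-0.83) and Hk2 (0.46). Leaving out single libraries ended calls: without scrambled replicate 1 the adjusted p was 0.0529 for p53 targets and 0.0977 for glycolysis, and each of the 4 lists kept its call in 3 of 6 such fits. Each lost it without scrambled replicate 2 and without TDP-43 siRNA replicate 2 (adjusted p = 0.0601 for the latter), and the RNA-binding protein and cell cycle lists also without scrambled replicate 3 (0.2 for cell cycle).

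The remaining lists did not pass camera's test after knockdown. Integrated stress response genes gave 11 rises and 4 falls of 26 (12 and 4 adjusted over the list alone; adjusted p = 0.0861), with Cebpb at 0.84 and Ddit4 at -0.84. Replication-dependent histone genes gave 6 and 0 of 15 (8 and 1; 0.0523), with Hist1h4b at 1.19, and extracellular matrix genes 5 and 15 of 28 (6 and 16; 0.0716), with Postn at -1.61, Thbs2 at -1.44 and Vcan at 1.13. Mitochondrial respiratory chain genes gave 1 and 5 of 29 (1 and 4; 0.107), with Cox5a at -0.50. Transcripts known as TDP-43 targets gave 6 and 3 of 19 (7 and 3; 0.727), with Poldip3 at -1.12, Sort1 at -0.87 and Rptor at 0.37. Unfolded protein response genes gave 4 and 1 of 19 (2 and 1 over the list alone, camera adjusted p = 0.967), with Pdia6 at -0.61. Immediate early genes gave 7 and 3 of 29 (7 and 3, camera adjusted p = 0.967), with Klf6 at 0.94 and Ctgf at -1.11. Purinergic signalling genes gave 4 and 3 of 24 (4 and 2, camera adjusted p = 0.737), with the nucleotide receptor gene P2ry1 at 1.15. Cholesterol synthesis genes gave 2 and 3 of 24 (2 and 3; 0.461), autophagy and lysosome genes 8 and 7 of 35 (8 and 7; 0.967), with Atg16l1 at 1.27 and Sqstm1 at 0.81, and glutamate genes 3 and 7 of 16 (3 and 7; 0.437), with Abat at -1.65.

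**Figure D2:**
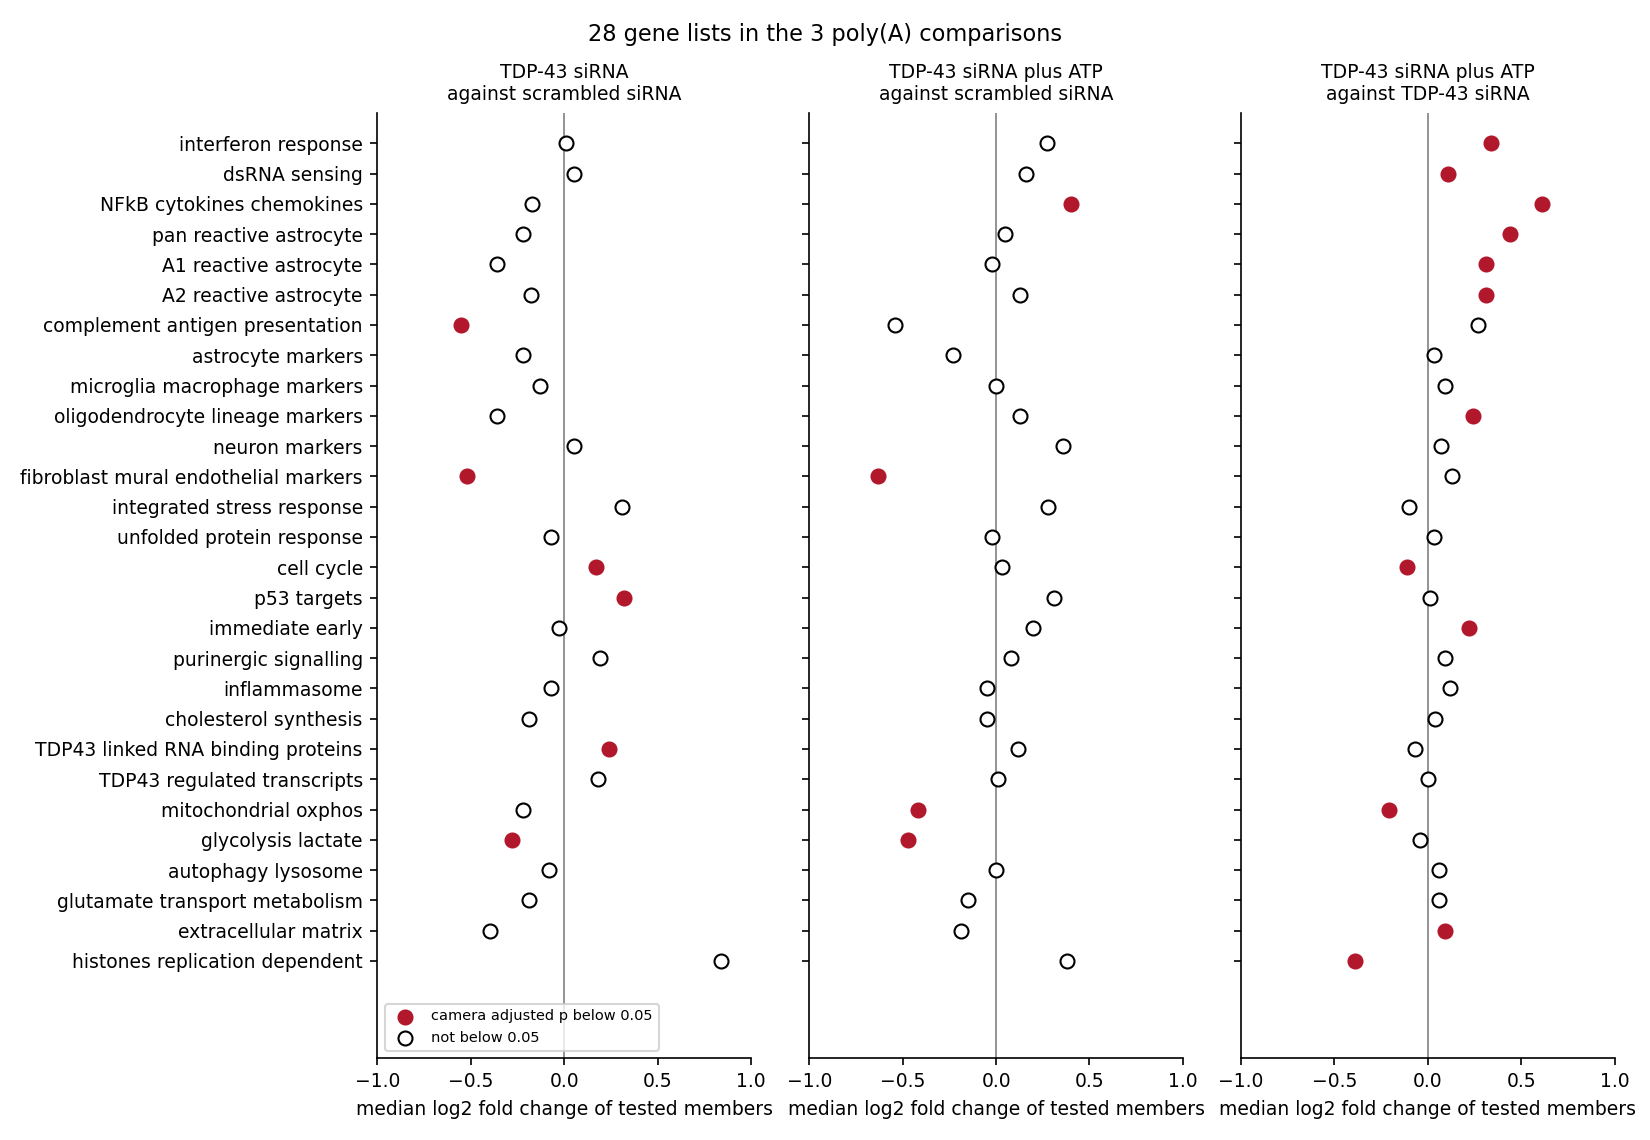
Median log2 fold change of the tested members (x axes) of 28 gene lists (y axis) in the 3 poly(A) comparisons; filled points have a camera adjusted p below 0.05 with the preset correlation and open points do not. After knockdown alone 6 lists passed, with ATP against scrambled siRNA 4, and between the groups with and without ATP 12. With an estimated correlation 0 passed. Other splits of the same libraries gave up to 5, 7 and 13 passing lists in the same order. Those splits mix both groups and keep part of the real difference, so they are no measure of chance.

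The second comparison set the cells given TDP-43 siRNA and ATP against scrambled siRNA. Among the largest rises were those of Osgin1 (2.77 ± 1.53 to 19.4 ± 1.34 CPM, SD, n = 3; log2 2.96), the cannabinoid receptor gene Cnr1 (2.92), the chemokine gene Cxcl1 (2.84), Kitlg (2.77), Akr1b8 (2.68), Adamts1 (2.52) and Gsta1 (2.52). Ctxn3 (-5.36), Wfdc1 (-4.95), Faim2 (-4.04), Lix1 (-4.03), Thrsp (-3.98), Pcp4 (-3.82), Prima1 (-3.80) and Megf6 (-3.69) fell furthest. NF-kappaB, cytokine and chemokine genes gave 11 rises and 0 falls of 30 (11 and 0 adjusted over the list alone; camera adjusted p = 0.0221, and adjusted p = 0.805 with an estimated correlation), among them Nfkb2 (0.87), Cxcl10 (1.11) and Cx3cl1 (0.76). Mitochondrial respiratory chain genes fell, with 1 rise and 18 falls of 29 (1 and 18 adjusted over the list alone; camera adjusted p = 0.000646, and adjusted p = 0.803 with an estimated correlation). Cox5a was at -0.84 and Cox6c at -0.85. Glycolysis genes gave 2 rises and 10 falls of 20 (3 and 13 adjusted over the list alone; 0.0177), with Pdk1 at -1.14 and Pfkp at 0.59. Fibroblast, mural and endothelial markers gave 1 rise and 8 falls of 15 (1 and 8 adjusted over the list alone; 0.0221, and 0.0747 without scrambled replicate 1), with Acta2 at -1.96. With an estimated correlation the adjusted p was 0.805 for both. Of 10 splits of the compared libraries, 5, the real one included, gave at least 4 passing lists. The other splits mix libraries of both groups and keep part of the real difference, so they do not show what chance gives.

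Interferon response genes gave 14 rises and 5 falls of 39 in that comparison (16 and 7 adjusted over the list alone; camera adjusted p = 0.128), with Gbp2 at 1.13, Rsad2 at 1.05 and Ifitm3 at -0.95, and double-stranded RNA sensing genes 5 rises and 1 fall of 22 (5 and 1; 0.232). Eif2ak2 rose by 0.89, Adar by 0.83 and Ifih1 by 0.39 on the log2 scale. Complement and antigen presentation genes, called after knockdown alone, did not pass here (1 rise and 8 falls of 22, camera adjusted p = 0.0635). Nor did p53 targets (10 and 1 of 19), RNA-binding protein genes linked to TDP-43 (4 and 0 of 26) or cell cycle genes (4 and 3 of 34). Their camera adjusted p were 0.0573, 0.128 and 0.793 in that order. In all, edgeR called 2106 rises and 2415 falls of 12096 genes, 425 and 594 of them at least 2-fold. Scaling by total counts moved the median of all genes to 0.24 and gave 4099 rises and 1400 falls.

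The comparisons with and without ATP used the same scrambled libraries. They shared 1519 rises and 1759 falls, and 5 genes were called in opposite directions. Simulated unchanged groups against these controls shared 0 of either, and independent lists would share 341 and 439. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.9, against 0.53 for the simulated groups, and their covariance was 0.49 against 0.04, a difference of 0.44. The 3 controls are too few to split, so part of the excess of shared calls over independent lists may come from sharing them; the difference of covariances leaves that part out.

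The third comparison asked what ATP added within knocked-down cells; ATP without knockdown was not analysed here. The largest rises were those of the G protein signalling regulator gene Rgs16 (6.19 ± 1.76 to 20.3 ± 1.78 CPM, SD, n = 3; log2 1.73), complement factor B gene Cfb (1.54), Tnfaip2 (1.51), the complement C5a receptor gene C5ar1 (1.34), Gbp5 (1.33), Klhdc8a (1.32), Hdac9 (1.29) and Nfatc2 (1.27). Car3 (-0.81), Tmem256 (-0.72), Vamp5 (-0.67), Pmepa1 (-0.63), Rps28 (-0.62), Synm (-0.62), Acot1 (-0.59) and Bcl2l11 (-0.59) fell. Of 30 NF-kappaB, cytokine and chemokine genes 10 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 3.82e-14, and adjusted p = 0.0637 with an estimated correlation), with Cx3cl1 at 0.83, Cxcl1 at 0.73 and Nfkb2 at 0.57. Of 39 interferon response genes 4 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 4.03e-10, and adjusted p = 0.399 with an estimated correlation), with Rsad2 at 0.85, Cmpk2 at 0.74 and Ifitm3 at 0.66. Cxcl10 rose from 35.1 ± 4.7 to 64 ± 1.29 CPM (log2 0.86, edgeR adjusted p = 0.0186), while Eif2ak2 (0.25, 0.423), Ifih1 (0.36, 0.16) and Ccl2 (0.72, 0.0941) did not pass.

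Immediate early genes gave 3 rises and 0 falls of 29 with ATP (7 and 1 adjusted over the list alone; camera adjusted p = 1.38e-06, and adjusted p = 0.0637 with an estimated correlation), namely Fosl1 (0.82), Dusp1 (0.64) and Nr4a1 (1.11). Pan-reactive astrocyte genes gave 2 and 0 of 13 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00134, and 0.226 with an estimated correlation), which were Cxcl10 and S1pr3 (0.60). A2 genes gave 2 and 0 of 11 (3 and 0; 0.0117), which were Cd14 and Ptx3, extracellular matrix genes 1 and 0 of 28 (6 and 0; 0.0053), and oligodendrocyte lineage markers 1 and 0 of 13 (3 and 0; 0.0326), which was Mbp (0.76). With an estimated correlation these 3 adjusted p were 0.223, 0.504 and 0.399. A1 genes (0 of 9 called; 0.00546, and 0.363 with an estimated correlation) and double-stranded RNA sensing genes (0 of 22 called; 0.0326, and 0.493) passed upwards with no member called over all genes. Cell cycle (0 of 34 called; median log2 -0.11, 0.000169, and 0.399 with an estimated correlation), mitochondrial respiratory chain (0 of 29; -0.21, 7.25e-07, and 0.226) and replication-dependent histone genes (0 of 15; -0.39, 4e-04, and 0.299) passed downwards in the same way. Of RNAs in the repeat table that also lack a poly(A) tail, the small nuclear and 7SL class had a median log2 of -0.38 (camera adjusted p = 8.16e-06, and 0.247 with an estimated correlation), and tRNA repeats one of -0.05 (0.777, and 0.94). Adjusted over the list alone, 1 double-stranded RNA sensing gene rose and 0 members of the other 4 lists changed. Single libraries carried 5 of the 12 calls: without TDP-43 siRNA replicate 2 those of sensing, A1 and matrix genes were lost, without TDP-43 siRNA replicate 3 that of A2 genes, without TDP-43 siRNA replicate 1 that of oligodendrocyte markers, and without replicate 2 of the group with ATP those of sensing genes and oligodendrocyte markers. Without scrambled replicate 1, which is in neither group compared, sensing genes (0.0511) and oligodendrocyte markers (0.0522) also lost theirs. Of 10 splits of the compared libraries, 4, the real one included, gave at least 12 passing lists. The other splits mix libraries of both groups and keep part of the real difference, so they are no measure of chance. In all, edgeR called 112 rises and 17 falls of 12096 genes, and 1523 had an unadjusted p below 0.05 where chance gives 605. The count moved with the libraries and the tool used: it was 817 with only the 6 compared libraries (431 rises and 386 falls), 501 without scrambled replicate 1 (275 and 226) and 431 with DESeq2 (267 and 164), and 21 to 53 with any single one of the 6 compared libraries left out.

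The repeat tables addressed whether TDP-43 loss changes transcripts of repetitive elements. In poly(A) RNA, the LTR retrotransposon element MLT1H rose from 41.2 ± 1.02 to 94.9 ± 12.4 CPM after knockdown (SD, n = 3; log2 1.20, SE 0.14, edgeR adjusted p = 0.00713). ORSL fell from 40.4 ± 20.6 to 6.69 ± 0.576 CPM (log2 -2.59, adjusted p = 0.00713) and RNIAP1b from 28.2 ± 10.4 to 8.02 ± 1.39 CPM (log2 -1.81, 0.0207). With ATP the log2 changes from scrambled siRNA were 0.85, -2.67 and -1.64 in the same order, with edgeR adjusted p of 0.0419, 0.0107 and 0.0419. These were the only 3 calls among 1137 elements in either comparison by edgeR, and 138 and 168 had an unadjusted p below 0.05 where chance gives 57. DESeq2 called 31 and 66. Leaving out 1 library gave 10 and 32 calls without scrambled replicate 1, 41 and 77 without scrambled replicate 2, and 2 and 1 without scrambled replicate 3. It gave 1, 0 and 0 calls without TDP-43 siRNA replicates 1, 2 and 3, and 0 without any library of the group with ATP. Between the groups with and without ATP, edgeR and DESeq2 both called 0 elements, and 5 had an unadjusted p below 0.05. The smallest p there belonged to 7SK (log2 -0.92), 7SLRNA (-1.43) and CR1-L3A_Croc (-0.82), each with an edgeR adjusted p of 1.

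**Figure D3:**
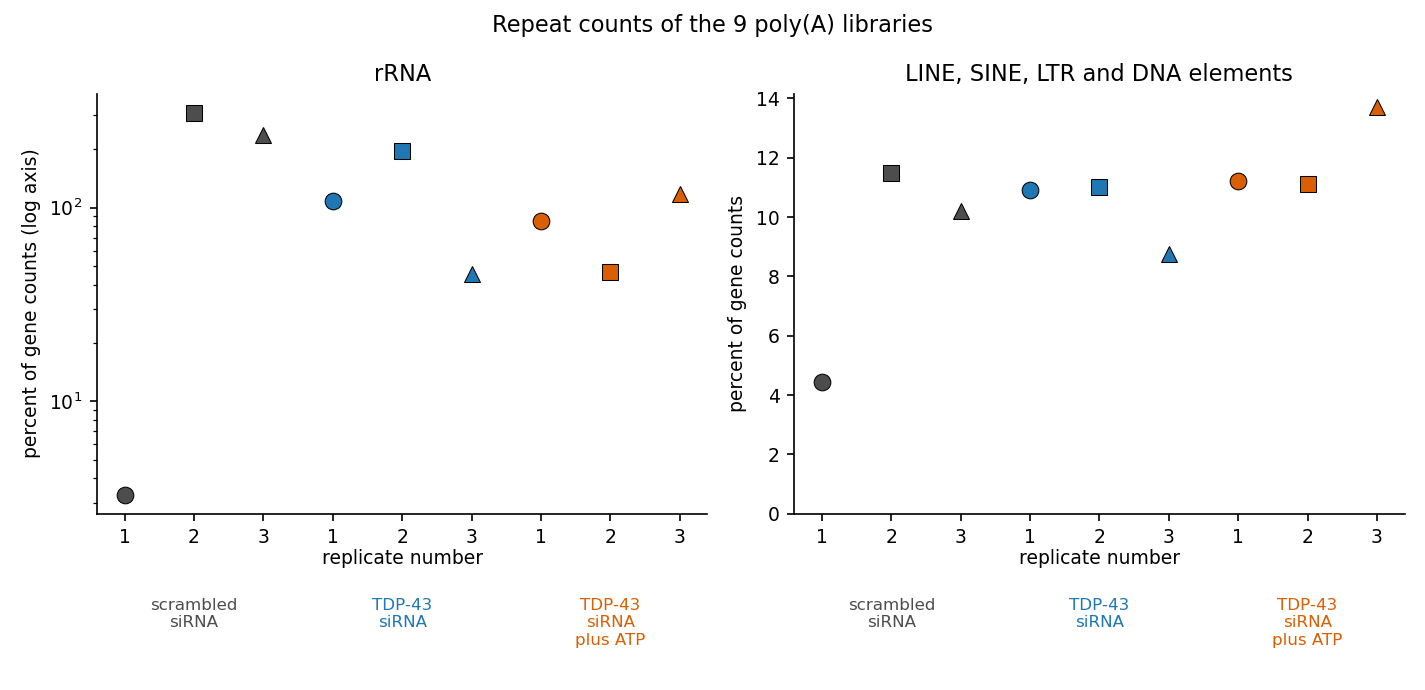
Counts of ribosomal RNA (left, log axis) and of LINE, SINE, LTR and DNA elements (right) in percent of the gene counts of the same poly(A) library (y axes), 1 point per library (x axes: replicate number within group). Scrambled replicate 1 stands at 3.3% for ribosomal RNA and 4.44% for transposons.

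Repeat counts per gene count varied widely within the scrambled group, where replicate 1 stood at 8.18% and the others at 321 and 249%. Repeats amounted to 193 ± 164% of gene counts with scrambled siRNA, 127 ± 76.8% with TDP-43 siRNA (SD, n = 3; exact permutation p = 0.6) and 95.8 ± 36.8% with TDP-43 siRNA and ATP (exact permutation p = 0.4). Without scrambled replicate 1 the differences from scrambled siRNA moved from -65.5 to -158 and from -97 to -189 percentage points, and both scrambled libraries left lay above every library of the other groups. Transposon counts alone were 8.7 ± 3.74, 10.2 ± 1.26 and 12 ± 1.45% in the same order; the groups with and without ATP did not overlap (exact permutation p = 0.1, the smallest possible), and the others did (0.7 and 0.3 against scrambled siRNA). Ribosomal RNA made up 79.8 to 96.2% of repeat counts in 8 of the 9 libraries and 40.4% in scrambled replicate 1. Scrambled replicate 1 held 3.3% ribosomal RNA and 4.44% transposon counts, where the other 8 libraries held 45.4 to 309% and 8.75 to 13.7%. Among repeat classes after knockdown, camera's test passed for LTR elements upwards (median log2 0.07, adjusted p = 0.0292) and for SINE (-0.12, 0.0267), small nuclear and 7SL (-0.36, 0.0115) and tRNA repeats (-0.50, 0.00043) downwards. With an estimated correlation these adjusted p were 0.463, 0.715, 0.546 and 0.463, and without scrambled replicate 1 the test passed for 0 classes. With the corrected class names, chosen after seeing the data, 0 classes passed upwards and 3 downwards, so the LTR call was lost. With ATP against scrambled siRNA it passed downwards for SINE (-0.19, 2.1e-05), small nuclear and 7SL (-0.95, 2.1e-05) and tRNA repeats (-0.62, 0.000765), each at an adjusted p of 0.477 with an estimated correlation, and for 1 class without scrambled replicate 1. Between the groups with and without ATP it passed for DNA (0.02, 0.0463), SINE (-0.08, 1.61e-05) and small nuclear and 7SL repeats (-0.38, 8.16e-06). The adjusted p with an estimated correlation was 0.0774, 0.579 and 0.247, and with the corrected names the DNA call was lost.

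The immunoprecipitation compared J2-bound RNA with input to ask which repeats were recovered as double-stranded RNA. In control cells, SINE elements took 50.5 ± 0.891% of repeat counts after immunoprecipitation and 27.4 ± 2.52% in input (SD, n = 3). LINE elements took 20.2 ± 1.46 against 11.1 ± 1%, LTR elements 18.6 ± 0.557 against 11.4 ± 0.965% and DNA elements 5.09 ± 0.0842 against 2.52 ± 0.248%. Small nuclear, 7SK and 7SL RNA took 1.33 ± 0.849 against 31.3 ± 2.46%, and ribosomal RNA 2.26 ± 1.96 against 14.2 ± 7.28%. TDP-43 siRNA cells gave 51.2 ± 0.577 against 27.5 ± 0.517% for SINE elements and 1.41 ± 0.732 against 30.1 ± 3.15% for the small nuclear class. Each of these differences gave an exact permutation p of 0.1, the smallest possible (0.15 adjusted over the classes in control and 0.129 in TDP-43 siRNA cells). Shares within a library depend on each other, so the fall of small nuclear and ribosomal RNA raises those of the other classes. On TMM-scaled counts the median log2 change of SINE elements was only 0.11 in control and 0.21 in TDP-43 siRNA cells. For LINE elements it was 0.07 and 0.10.

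**Figure D4:**
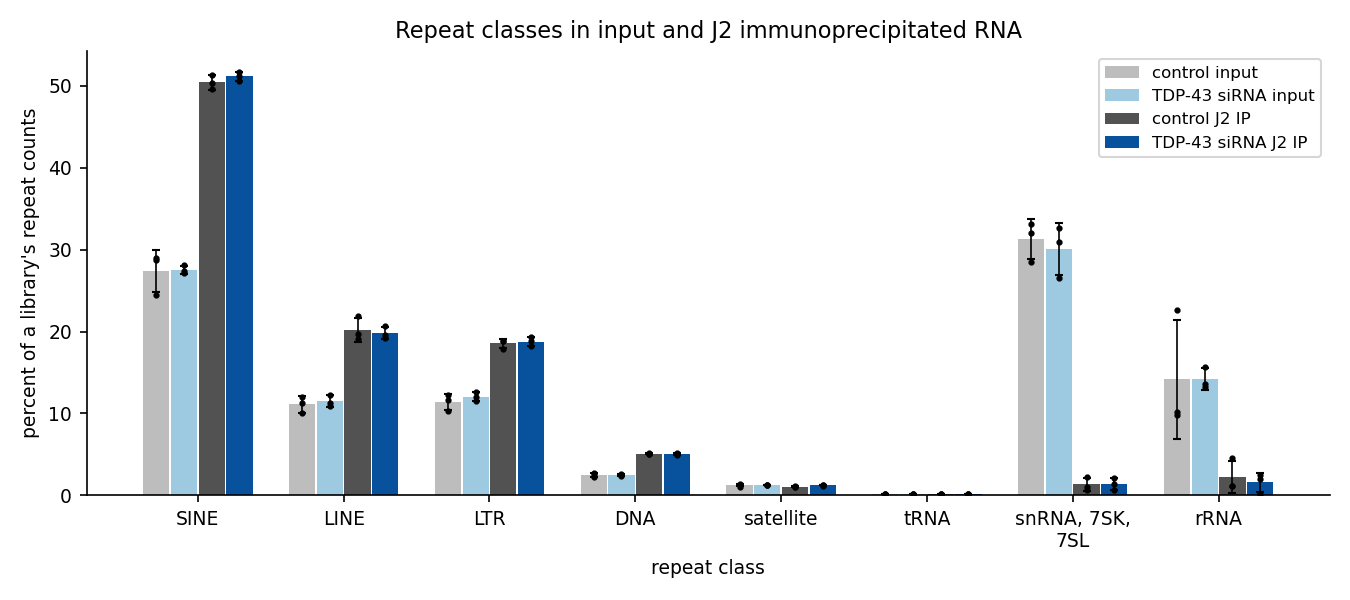
Share of each library's repeat counts (y axis, percent) taken by 8 repeat classes (x axis) in input and J2 immunoprecipitated RNA of control and TDP-43 siRNA cells; bars are means, error bars SD (n = 3) and points libraries. The share of SINE elements rose from 27.4 to 50.5% in control cells as that of small nuclear, 7SK and 7SL RNA fell from 31.3 to 1.33%. Shares depend on each other, and the median log2 change of SINE elements there was 0.11.

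Of 1176 elements, edgeR called 144 higher and 205 lower after immunoprecipitation in control cells and 148 and 202 in TDP-43 siRNA cells. The largest rises in control cells were those of Tigger1a_Art (log2 3.59), MER70C (3.23), UCON58 (3.17), UCON28a (2.87) and MLT1G-int (2.76), and in TDP-43 siRNA cells those of UCON58 (4.20), UCON65 (3.16), MER70C (3.15), MER70B (2.64) and UCON28a (2.57). In both, 3 tRNA elements had 0 counts in the immunoprecipitated libraries. Against a floor of 3 counts over the group, which covers counting error only, tRNA-Ser-TCA_m_ was at least 2310-fold lower in control and at least 2450-fold lower in TDP-43 siRNA cells, tRNA-Ser-TCG at least 132-fold and 98-fold lower, and tRNA-Leu-TTA_m_ at least 70.7-fold and 104-fold lower. The small nuclear RNA 7SK fell by 8.30 and 7.87 on the log2 scale, U1 stood at log2 -5.83 in TDP-43 siRNA cells, and MamGypLTR2b had 2 counts against 626 in control cells. The enrichments shared 106 rises, 145 falls and 0 opposite calls, where independent lists would share 18.1 and 35.2, and correlated across elements at r = 0.7. As classes, tRNA and small nuclear repeats fell in both (camera adjusted p with an estimated correlation 0.0291 in control and 0.048 in TDP-43 siRNA cells), with 16 of 40 tRNA elements lower in control cells although the share of the tRNA class was 0.178 against 0.174%. Satellites fell in control cells (6 of 9 lower; camera adjusted p = 0.00394, and 0.0291 with an estimated correlation) and not past the threshold in TDP-43 siRNA cells (0.064). LINE and SINE classes passed upwards in both, but their adjusted p with an estimated correlation was 0.139 and 0.535 in control and 0.162 and 0.371 in TDP-43 siRNA cells. LTR elements gave 48 rises and 94 falls in control (median log2 -0.10, camera adjusted p = 0.705) and 47 and 88 in TDP-43 siRNA cells (-0.05, 0.657), although their share of counts rose as those of small nuclear and ribosomal RNA fell. DNA elements did not pass (camera adjusted p = 0.147 and 0.176, and 0.219 and 0.252 with an estimated correlation), but did upwards with the corrected class names chosen after seeing the data (0.0178 and 0.0248). Scaling by total counts shifted the median of all elements to 0.68 and 0.65 and gave 477 rises and 106 falls in control and 463 and 93 in TDP-43 siRNA cells.

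How many elements were called after knockdown in total RNA depended on the libraries fitted and the tool. In input, edgeR and DESeq2 called 0 of 1176 elements, and 17 had an unadjusted p below 0.05 where chance gives 59. RMER6C (log2 0.41), NICER2v_Rn_I-int (0.46) and MER2 (-0.13) had the smallest p, each with an edgeR adjusted p of 1. With the 6 input libraries fitted alone edgeR called 164 elements, 90 higher and 74 lower. In the fit of all 12 libraries, camera passed LTR upwards (median log2 0.03, adjusted p = 0.000932) and DNA (-0.06, 0.00586), SINE (-0.05, 0.000932) and tRNA repeats (-0.08, 0.0238) downwards. With an estimated correlation the camera adjusted p were 0.0905, 0.0905, 0.506 and 0.255 in the same order. After J2 immunoprecipitation, 2 LTR elements rose with knockdown: RLTR40 from 346 ± 19.8 to 585 ± 67.5 CPM (SD, n = 3; log2 0.76, SE 0.09, edgeR adjusted p = 0.00461) and RLTR31M from 23 to 291 counts over the group (log2 3.51, SE 0.60, adjusted p = 0.0493). By edgeR 207 elements had an unadjusted p below 0.05 where chance gives 59, but the groups did not overlap for 8.76%, where chance gives 10%. DESeq2 called 76 elements (31 higher and 45 lower), edgeR called 0 with the 6 immunoprecipitated libraries alone, and leaving out any single one of these 6 gave 8 to 55. No repeat class passed camera's test. The smallest adjusted p, 0.172, was that of satellites (median log2 0.30), which passed limma's fry (adjusted p = 0.0314). Their share was 1.23 ± 0.025% after knockdown and 1.06 ± 0.0746% in control cells (SD, n = 3), with the groups fully apart (exact permutation p = 0.1, the smallest possible, and 0.9 adjusted over the classes).

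The difference of the enrichments tested whether knockdown changed the relative make-up of the repeats that J2 recovered. Each library was scaled on its own repeat counts, so a general change in the amount of double-stranded RNA could not be seen. Gene counts were available for the poly(A) libraries only, so Tardbp was not checked in the immunoprecipitation. By edgeR 0 of 1176 elements passed and 88 had an unadjusted p below 0.05 where chance gives 59, while DESeq2 called 10. Without control immunoprecipitated replicate 1 edgeR called 7, without TDP-43 siRNA immunoprecipitated replicates 1 and 3 it called 2 and 10, and without any other single library 0. RLTR40 (log2 difference 0.64, SE 0.13), MER123 and UCON48 had the smallest p, each with an edgeR adjusted p of 0.327. No class passed (smallest camera adjusted p = 0.14). Across 1128 elements, which are not independent replicates, the knockdown log2 fold changes in poly(A) RNA correlated with those in input at r = 0.21 (rho 0.16) and with those in immunoprecipitated RNA at r = 0.1 (rho 0.04). In simulated data for the immunoprecipitated comparison, 32.8% of elements changed 2-fold and 71.2% of those changed 4-fold were recovered. That simulation used the spread fitted to all 12 libraries (biological coefficient of variation 0.413), where the immunoprecipitated ones alone had 0.593. Recovery in the real libraries may therefore be lower.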

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

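No group held enough libraries for a test of single outliers, and edgeR and camera passed no element or class in the test of a difference between the enrichments (88 elements at an unadjusted p below 0.05), where DESeq2 called 10 elements. Of the tests in this part, those of a swapped library, of ribosomal RNA, of poly(A) selection, of fibroblasts and of mural cells were chosen only after the result, or a related value, had been seen.

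Scrambled replicate 1 held far fewer repeat counts per gene count than the other 8 poly(A) libraries. A swap with a knockdown library is argued against by its Tardbp level of 179 CPM. Carry-over of ribosomal RNA as the only difference is argued against by its transposon counts, 4.44% of gene counts where the lowest other library held 8.75%. Stricter poly(A) selection of that library may be the source: its replication-dependent histone mRNAs, which lack a poly(A) tail, summed to 180 CPM, below the 195 to 253 CPM of the others, though group medians of that list had been seen before. Among the others that sum did not track ribosomal RNA closely. It was 239 CPM at 45.4% in TDP-43 siRNA replicate 3, 195 CPM at 46.6% in replicate 2 with ATP and 224 CPM at 309% in scrambled replicate 2, so this is weak support. A difference in the cells themselves was not tested.

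Fibroblast, mural and endothelial markers fell after knockdown. An equal loss of all fibroblasts, with expression per cell unchanged, would lower Acta2, Tagln and Myh11 as far as Col1a1 and Col3a1. The log2 change of the former differed from that of the latter by -1.54 on average. But the former were the 3 falls of the marker list with the smallest p. Genes picked for their fall tend to fall further than others, so this difference does not settle whether such a loss took place. A loss limited to fibroblasts rich in contractile genes, or a change in collagen expression per cell, would not be seen by this test. Fewer mural cells cannot be told apart from lower expression: the difference from Pdgfrb and Des was -1.87, but Des averaged 4.11 CPM, too near the floor. A candidate explanation is lower expression of actin cytoskeleton genes across the cultures, whose added list, without those 3 genes, had a median log2 change of -0.56 (0 rises and 15 falls of 22; camera adjusted p = 3.39e-06, and adjusted p = 0.104 with an estimated correlation). Which cells of the cultures expressed these genes was not measured. Their changes were uneven, with Myl9 at -1.52 and Tpm2 at -1.23, but Actb at -0.44 and Actg1 at -0.11 (edgeR adjusted p = 0.665). Fewer contractile cells would lower the list too, so it cannot tell these explanations apart and the source stays open.

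No element was called between knockdown and control input with all 12 libraries, but 164 of 1191 were with the 6 input libraries alone, at a median absolute log2 change of 0.31, with 4 at least 2-fold. A spread shared with more variable J2 libraries may account for this: the biological coefficient of variation was 0.593 in J2 and 0.0797 in input libraries, a ratio of 7.43. Of LTR elements 65 were higher and 20 lower, and of DNA elements 5 and 30. Of the 10 splits of the 6 input libraries 1, the real one, gave as many calls, and the highest other gave 1. The other splits mix libraries of both groups and keep part of the real difference, so they do not show what chance gives. Besides, 10 splits are too few for a share under 0.05.

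The libraries of each comparison of 3 against 3 were also split in the other ways, 10 splits in all, which are too few for a share under 0.05. Each other split mixes libraries of both groups. It keeps part of the real difference and adds the rest to the spread within groups. Its counts therefore do not show what unchanged groups would give, either for calls or for lists and classes. For genes, knockdown gave 4154 calls, knockdown with ATP 4521 and ATP within knockdown 129, with 0 as the highest other; for each, 1 split gave as many. For gene lists the real splits gave 6, 4 and 12, the highest others 5, 7 and 13, and 1, 5 and 4 splits gave as many. The counts of lists passing with ATP and for ATP within knockdown were thus reached or exceeded by other splits. Poly(A) repeats gave 3 and 3 calls with 0 as the highest other (1 split each), and 0 with 0 for ATP within knockdown (10 splits). Their classes gave 4, 3 and 3 against 4, 4 and 4 (4, 4 and 3 splits). Input gave 0 calls against 0 (10 splits) and 4 classes against 5 (4 splits). For classes in poly(A) RNA and input too, other splits gave at least the real counts. The enrichments gave 349 and 350 calls against 0 and 0, and 5 and 4 classes against 3 and 2 (1 split each). In immunoprecipitated RNA 9 splits gave at least the real 2 calls and the highest other gave 30, which points to a structure among these libraries or to a shared spread too small for them (coefficient 0.413 over all 12 against 0.593); neither was tested, and edgeR called 0 with these 6 alone. Classes gave 0 against 0 (10 splits). For the difference of the enrichments all 100 drawn splits gave at least the real 0 calls and 0 classes, the highest others giving 7 and 3. Where the real count is 0, every split gives as many by construction, so those counts test nothing.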

How the results depend on the processing

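The alternatives with scrambled replicate 1 left out of more fits, the corrected classes and the transposon share were chosen after seeing the data; the others were planned, and where a value moved the cause was not tested unless named. Of the alternatives for named genes, elements, lists and classes 5825 kept the side of the threshold, 405 lost and 68 gained the call, and 3 reversed. A reversal was counted only where the main result or the alternative was called. The 5825 may thus hold changes of direction in results called in neither. Reversed were SINE elements in poly(A) RNA after knockdown without scrambled replicate 1 (camera adjusted p = 0.374, against 8.65e-05 without scrambled replicate 2). DNA elements in the enrichments reversed with fry (adjusted p = 0.00375 in control, 0.00713 in TDP-43 siRNA cells), a test that does not compare a class with others. Gene counts after knockdown stayed within 1.5 times under each alternative except a minimum log2 change of 1, which leaves by construction 957 (knockdown), 1019 (with ATP), 30 (ATP within knockdown), 1 (immunoprecipitated RNA), 185 and 172 (enrichments). For ATP within knockdown the count of 129 became 431 with DESeq2, 817 with only the compared libraries and 501 without scrambled replicate 1. For poly(A) repeats after knockdown and with ATP the counts of 3 became 31 and 66 with DESeq2, 0 and 1 with total counts, 0 and 0 with only the compared libraries, 1 and 1 with gene-table library sizes and 33 and 32 with these and without scrambled replicate 1; with ATP they became 13 with upper-quartile factors and 16 with at least 10 CPM. In immunoprecipitated RNA the count of 2 became 76 with DESeq2, 0 with only the compared libraries and 1 with upper-quartile factors or no filter. Input went from 0 to 164 with only the compared libraries, the difference of the enrichments from 0 to 10 with DESeq2, and the enrichments to 583 and 556 with total counts. With an estimated correlation 0 gene lists passed in each comparison and 0 classes in poly(A) RNA and input, and 3 and 2 in the enrichments; fry passed 8 lists with ATP, 3 for ATP within knockdown, 0 classes in poly(A) RNA and input and 1 in immunoprecipitated RNA. Replicate numbers did not pair the libraries (correlations of deviations -0.15 to 0.12 for genes, -0.25 to 0.14 for poly(A) repeats, -0.1 to 0.08 for the immunoprecipitation), and a replicate block gave 68 calls for ATP within knockdown, 1 for poly(A) repeats with ATP and 1 in immunoprecipitated RNA, moving no other count by over 1.5 times. Leaving out each compared library gave 21 to 53 genes for ATP within knockdown, 0 to 41 and 0 to 77 poly(A) repeats after knockdown and with ATP, 8 to 55 in immunoprecipitated RNA, 0 to 10 for the difference of the enrichments, 2 to 7, 4 to 7 and 9 to 16 gene lists in the 3 comparisons, and 0 to 4, 1 to 4 and 2 to 4 poly(A) classes. It gave 0 to 1 classes for the difference of the enrichments, 14 to 30 class shares whose groups did not overlap, differences in repeats per gene count of -158 to -1.28, -189 to -32.7 and -67.7 to 8.83 percentage points, and correlations of knockdown effects of 0.09 to 0.27 (poly(A) and input) and 0.02 to 0.14 (poly(A) and immunoprecipitated RNA). Depth was lowest in the immunoprecipitated libraries, at 1.85 to 3.37 M counts, and was not separated from their spread as a limit.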

Other observations

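The genes and lists of this part were chosen only after main results had been seen, though the test of the actin cytoskeleton list was set before that list had been tested. Caprin1, which encodes a stress granule protein, fell as far as Tardbp. It went from 376 ± 49.1 CPM (SD, n = 3) to 54.9 ± 8.66 CPM with TDP-43 siRNA (log2 -2.78, SE 0.14, edgeR adjusted p = 1.83e-09). With TDP-43 siRNA and ATP it stood at 56.1 ± 5.04 CPM (log2 -2.74). Whether the siRNA acted on Caprin1 directly or through TDP-43 cannot be told apart in this design. RGD1309870, listed under the synonym of Spmip7 in the reference, had 0 counts in the 3 scrambled libraries and 708 with TDP-43 siRNA (11.4 ± 5.24 CPM). Against a floor of 3 counts over the group this was at least 217-fold higher, and with ATP, at 490 counts, at least 124-fold higher. Coro2a, Plvap, RGD1309870 and Vstm5 were the 4 genes with 0 counts in all scrambled and at least 10 in each TDP-43 siRNA library. Against TDP-43 siRNA and ATP there were 6, namely Kcnj6, Nxpe1, Plvap, RGD1309870, Slc17a3 and Vstm5, and 0 genes showed the reverse in either case.

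Of 22 tested genes of the actin cytoskeleton 15 fell and 0 rose after knockdown (camera adjusted p = 3.39e-06, and adjusted p = 0.104 with an estimated correlation). Among the falls were Myl9 (log2 -1.52), Tpm2 (-1.23), Tpm1 (-1.15), Cnn1 (-1.09), Vcl (-1.04), Flna (-0.70) and Actb (-0.44). The other 7 were not called, among them Tpm4 (0.28), Smtn (0.15), Cald1 (0.13) and Srf (-0.08). With ATP 2 rose and 15 fell of 22 from scrambled siRNA (median log2 -0.44, camera adjusted p = 4.91e-05, and adjusted p = 0.154 with an estimated correlation). Between the groups with and without ATP 1 of 22 rose and the list did not pass (adjusted p = 0.213).

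Osgin1, Srxn1, Slc7a11, Gsta1 and Akr1b8, among the largest rises, are known targets of NRF2, the transcription factor of the oxidative stress response. The hypothesis that a wider NRF2 response may accompany knockdown was tested on a list of other targets, which had a median log2 change of 0.28 with 12 rises and 4 falls of 29 (camera p = 0.00696, and adjusted p = 0.248 with an estimated correlation). Hmox1 rose by 1.59, Gstp1 by 0.98, Txnrd1 by 0.83 and Nqo1 by 0.48, while Gsta4 fell by 0.71 and Ugdh by 0.39. The value of Sqstm1, 1 of the members, had been seen; without it the median was 0.27 and the camera p 0.0137. With ATP against scrambled siRNA the list did not pass (adjusted p = 0.0764).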
